A study of Homo sapiens with 6 samples.

How the data were processed

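Gene expression was measured in human endometrial stromal cells, the fibroblast-like cells of the uterine lining, at early passage. Per the labels' protocols, the cells were infected with a nonreplicative retrovirus carrying Jag1 or with the empty vector, and total RNA was taken on day 3 after infection. There were 3 arrays of Jag1 cells and 3 of control cells, each hybridised with biotin-labelled RNA to an Affymetrix expression array of 54675 probe sets. The labels do not say whether the replicates came from separate cultures or donors, so p-values measure the spread between these samples, which may be technical. Groups and replicate numbers were taken from the sample titles. For the third control, another label repeats the number 1, and the title's number was used.

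The deposited values were intensities on a linear scale, 1 signal per probe set and array. The authors made them with MAS5, per the submitters' processing notes; its version and settings were not given in the sources used here. The mean signal, with 2% of probe sets trimmed at each end, lay between 250.03 and 250.04 in every array, so each array had already been scaled to a common level. Such scaling equalises the overall brightness of the arrays, and a change shared by most transcripts would not be seen. No probe-level data were used here, and the assignment of probes to transcripts was the array design's own.

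Probe sets were named through the platform's annotation table, with symbols checked by Entrez identifier against the RefSeq gene table of assembly GRCh38.p14, used for names only. Of the 54675 probe sets, 62 were array controls, 41091 had 1 gene, 1801 had several genes, and 11721 had none in the table or were unlisted there. No symbol needed updating, and 54 probe sets whose identifier was missing from the gene table kept the symbol of the annotation. Genes on the Y chromosome alone and the X-inactivation transcripts, covering 59 probe sets, were left out of the gene-level test. Other X-linked genes were kept. Probe sets with several genes or none were tested only in a separate fit over 54554 probe sets.

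Signals were analysed as log2(signal + 16). All log2 changes are Jag1 minus control on this scale, which understates the change of dim genes. For each gene the probe set with the highest mean over the 6 arrays was used, and a probe set of the cross-hybridising _x_at kind only where a gene had no other. This gave 19740 genes. They were tested with limma (lmFit and eBayes with an intensity trend) without a block, and p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. Single values per array were compared by two-sided exact permutation tests, which with 3 arrays against 3 cannot give a p below 0.1. The number of arrays limits the precision of every value. R 4.3.3, limma 3.58.1, Python 3.11.15 and pandas 2.3.3 were used.

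Gene lists were written from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 25 lists held 829 entries, of which 779 were measured. JAG1 was left out of every list. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the 25 lists, and again with a correlation estimated from the residuals. The rule named every JAG1 probe set, the 8 largest rises and 8 largest falls among genes past the threshold with groups apart, and 4 members of each list past its test with the smallest p. It also named 4 members each of the Notch target and decidualization lists, with HES1, HEY1, HEYL, PRL and IGFBP1 in any case. Other genes were chosen after their values were seen: HES7, CDKN2B, NFATC2, TGFB2, STC2, NID2, SMAD6, TGFBR2, TNFAIP3, IER3, DUSP4, KRT19, SPINT2, ANPEP, VEGFC, NEFM and the genes named only for passing with the block when adjusted over the list alone in the report, and every gene of the additional observations that is not named in the report.

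The titles number the arrays 1 to 3 in each group, and whether the numbers pair the samples was checked before the fits were compared. Over the 5000 genes with the highest mean, deviations from the group mean correlated at 0.662, 0.117 and 0.639 between arrays of the same number. All 3 exceeded the limit of 0.1 set beforehand, so the numbers were taken to pair the samples. The second pair was barely above it. Jag1 replicate 1 correlated more closely with control replicate 2, at 0.192, than the second pair did with each other. Jag1 replicate 2 also exceeded the limit with control replicate 3, at 0.103, so the limit does not single out the second pair. The pairing therefore comes from the numbers in the titles and from this check, not from a statement in the labels. A fit with the replicate number as a block is given where it changed a result.

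The fits were tested on simulated data before use, with independent noise drawn for the 19740 genes from their measured means and spreads. In 10 simulations, 200 genes with a mean at or above the median were changed. Without the block, 36.3% of the genes changed by 1 on the log2 scale and 98.2% of those changed by 2 were recovered, and 5.2% of calls were false. With the block these shares were 26.6%, 97.6% and 6.2%. A cell cycle list shifted by 0.6 was recovered by the list test in 10 of the 10 simulations, and unchanged lists were called in 1 of 240 tests. The simulated genes were not correlated and no replicate effect was planted. The rates therefore do not apply to correlated lists, such as the measured cell cycle list with an estimated correlation of 0.265. The lower recovery with the block was likewise set by the simulation.

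Alternatives were other pseudocounts, a filter on dim genes at the 40th percentile, quantile normalization, median scaling, every probe set, the mean of a gene's probe sets, no intensity trend and array weights. The replicate block, alone and with quantile normalization, other thresholds, and leaving out each array in turn were further alternatives. A covariate for RNA quality and a block fit without the second pair were added after seeing the data.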

Results

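The series compared endometrial stromal cells infected with a Jag1 retrovirus with cells infected with the empty virus, to find the genes whose expression depends on Jag1. JAG1 is a membrane ligand that activates Notch receptors on neighbouring cells. There were 3 arrays per group. The median signal of an array ranged from 42.8 to 56.3, and Spearman correlations between arrays ranged from 0.951 to 0.976. Over 27 bacterial control probe sets, for RNAs absent from human cells, the median signal was 4.82, the 95th percentile 28.7 and the highest 66.2. The 3'/5' signal ratio of ACTB, a measure of RNA integrity, was 1.33 ± 0.289 (SD, n = 3) in Jag1 arrays and 1.19 ± 0.216 (SD, n = 3) in controls (exact permutation p = 0.5). For GAPDH it was 1.01 ± 0.0650 and 1.00 ± 0.0400 (SD, n = 3 each; exact permutation p = 0.9). Ribosomal RNA control probe sets had mean signals of 203 and 192 in replicate 1 of the Jag1 and control groups, against 59.5 to 83.3 in the other 4 arrays.

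JAG1 itself was about 8-fold higher in cells given the Jag1 virus. Its brightest non-cross-hybridising probe set, 216268_s_at, had a signal of 3657 ± 20.8 in Jag1 arrays against 453 ± 113 in controls (SD, n = 3 each). The log2 change was 3.00 ± 0.213 (SE), with a limma Benjamini-Hochberg adjusted p of 0.00455 over all probe sets. Probe sets 209099_x_at (log2 change 2.91, limma adjusted p = 0.00303), 231183_s_at (2.98, adjusted p = 0.0379) and 209098_s_at (2.37, adjusted p = 0.0236) also rose. In each of these 4 the groups did not overlap, which gave an exact permutation p of 0.1, the smallest possible. The remaining pair, 209097_s_at and 229924_s_at, had mean signals of 4.17 and 9.25 in Jag1 arrays and 6.12 and 5.43 in controls, within the range of the bacterial controls. The labels do not state the species or extent of the inserted Jag1, and the probes do not separate the viral transcript from the cells' own. Without Jag1 replicate 2 or Jag1 replicate 3, the change of 216268_s_at was still 3.00, but it no longer passed the threshold over the 54554 probe sets (limma adjusted p = 0.0565 and 0.0635).

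Without the replicate block, cells given Jag1 showed a small set of strongly altered genes, most of them higher. With the block, 31 of the 48 genes past the threshold were higher, a smaller share. KCNE4, a regulatory subunit of potassium channels, rose from a signal of 41.0 ± 18.9 to 788 ± 103 (SD, n = 3 each). HEYL, a helix-loop-helix repressor activated by Notch, rose from 56.9 ± 15.6 to 987 ± 306. COL5A3, a chain of type V collagen, rose from 216 ± 25.5 to 2327 ± 159, and ID4, an inhibitor of helix-loop-helix transcription factors, rose from 171 ± 33.3 to 1575 ± 160. The control means of KCNE4 and HEYL lay within the range of the bacterial controls. Among the 4 genes that fell without the block, FIBIN, a secreted factor first described in fin development, went from 2719 ± 718 to 666 ± 112. The heparan sulfate proteoglycan SDC4 went from 1403 ± 271 to 370 ± 39.2.

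In all, 26 of 19740 genes passed an adjusted p of 0.05 without the block (limma, Benjamini-Hochberg), 22 higher and 4 lower. That made 84.6% of them higher. Without JAG1, 21 were higher. The log2 changes of the strongest rises were 3.87 ± 0.300 (SE) for KCNE4, 3.75 ± 0.287 for HEYL, 3.34 ± 0.167 for COL5A3 and 3.10 ± 0.195 for ID4. They were followed by STK32B, a serine/threonine kinase, at 3.05 ± 0.348, by JAG1, by EBF1, a transcription factor of B cell and mesenchymal development, at 2.90 ± 0.312, and by OLFML2B, an olfactomedin domain matrix protein, at 2.88 ± 0.278. The control mean of STK32B, 19.5 ± 4.63 (SD, n = 3), also lay within the range of the bacterial controls. The sizes and ranks of such changes depend on the pseudocount: that of STK32B was 3.78 with a pseudocount of 1, and 2.04 with 64, where it did not pass (limma adjusted p = 0.0613). Limma adjusted p-values of these genes ranged from 0.000499 for COL5A3 to 0.0265 for STK32B. Other probe sets of these genes did not all agree. In the fit over all probe sets, COL5A3 also rose by 218975_at (log2 change 3.72), ID4 by 209292_at (2.68) and EBF1 by 232204_at (2.56), with limma adjusted p-values of 0.00303, 0.0135 and 0.0135. KCNE4 did not pass by 1552507_at (1.84) or 1552508_at (2.31), ID4 by 209293_x_at (1.49) or 226933_s_at (1.76), or EBF1 by 229487_at (2.07), with limma adjusted p-values of 0.767, 0.457, 0.725, 0.417 and 0.0567. ID4 by 229386_at and EBF1 by 233261_at had mean signals within the range of the bacterial controls, with changes of 0.22 and -0.15. The 4 falls were FIBIN (log2 change -1.98), SDC4 (-1.86), NET1 (-1.18), and KRTAP1-3, a hair keratin-associated protein (-1.17). By its tested probe set, 220978_at, KRTAP1-3 had signals of 25.3 ± 1.77 in controls and 2.39 ± 1.05 in Jag1 arrays, both within the range of the bacterial controls. By 234880_x_at, of the cross-hybridising kind, it had 276 ± 203 and 103 ± 71.7, a log2 change of -1.31 that did not pass (limma adjusted p = 1.00). All 26 genes changed at least 2-fold on the log2(signal + 16) scale and had groups that did not overlap. Over all genes, 10% had groups that did not overlap, which is the share expected for 3 against 3 when all 6 arrays are exchangeable; correlated pairs alter that share, and it was not computed for them. At an unadjusted limma p under 0.05 there were 1130 genes, 501 higher and 629 lower. With no change in any gene, a share of 0.05 of the 19740 would be expected, so this count is only a little above chance. The median log2 change of all genes was -0.02. Of the 13522 probe sets with several genes or none, 0 passed the threshold in limma's fit over all probe sets, where 27 passed in all.

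**Figure D1:**
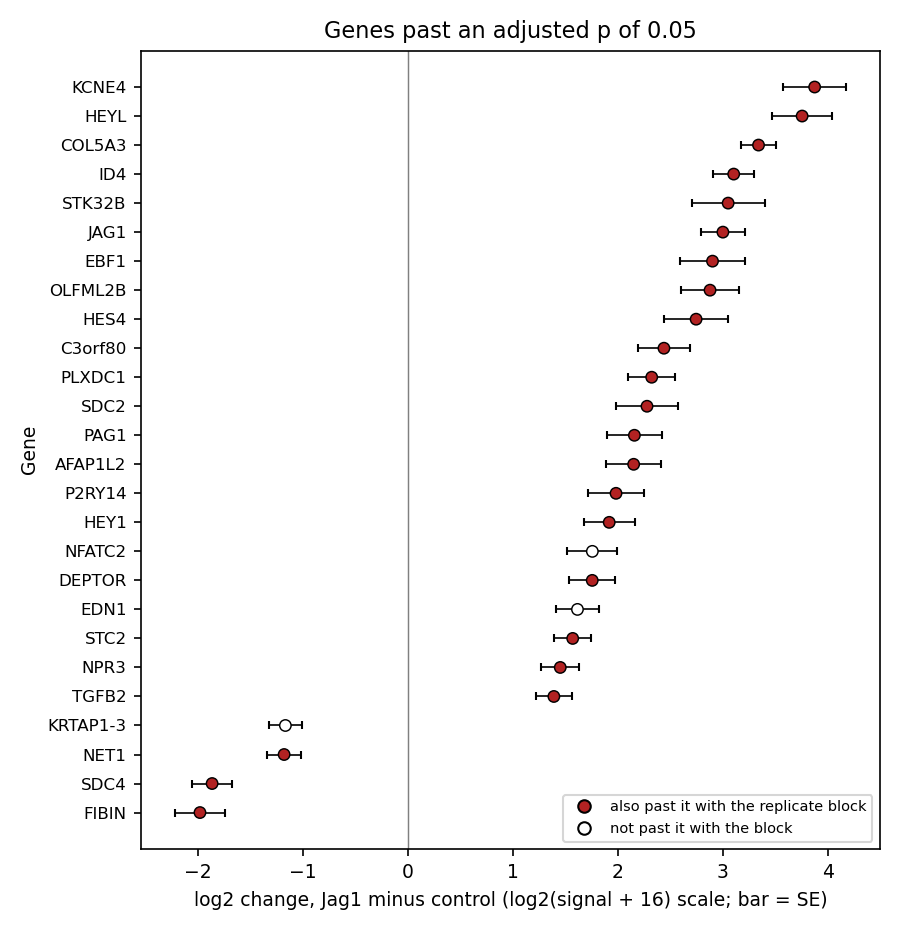
Log2 change, Jag1 minus control on the log2(signal + 16) scale, of the 26 genes past an adjusted p of 0.05 (limma), with bars for 1 SE and 3 arrays per group. Filled points are the 23 genes that also passed with the replicate number as a block; changes range from -1.98 for FIBIN to 3.87 for KCNE4.

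With the replicate number as a block, 48 genes passed, 31 higher and 17 lower, and 64.6% were higher. Of these, 23 were among the 26 genes above, and KRTAP1-3, EDN1 and NFATC2 no longer passed (limma adjusted p = 0.0958, 0.0536 and 0.0536). The largest fall with the block was that of NEFM, a neurofilament gene (log2 change -2.58). The counts were also lower with any 1 array left out. Then 10, 5 and 4 genes were higher without Jag1 replicate 1, 2 or 3. Without control replicate 1, 2 or 3, 6, 6 and 21 were higher, and in these fits 0, 1, 0, 0, 0 and 2 were lower. Dependence on particular arrays and the loss of samples cannot be told apart by these counts. COL5A3, HEYL, ID4 and JAG1 passed in all 6 of these fits, and KCNE4 in 5. Among the genes that passed in 0 of the 6 were HEY1, EDN1, TGFB2, NET1, KRTAP1-3 and NFATC2. These calls were adjusted over the 19740 genes, and the p-values given for JAG1 above over all probe sets.

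Notch target genes rose as a group. Of 25 measured, 20 were higher, 12 of them in every numbered pair of arrays, and 3 passed the test: HEYL, HES4 and HEY1, all repressors of the Hes and Hey family. HES4 rose from a signal of 84.0 ± 40.4 to 623 ± 93.0 and HEY1 from 216 ± 51.5 to 861 ± 209 (SD, n = 3 each), with log2 changes of 2.74 ± 0.308 and 1.92 ± 0.244 (SE; limma adjusted p = 0.0265 and 0.0383). HES4 was measured only by a probe set of the cross-hybridising kind, and the second HEY1 probe set, 218839_at, gave a larger change of 3.24. HES1, the best known target, had signals of 496 ± 24.1 in Jag1 arrays and 114 ± 68.0 in controls, a log2 change of 2.16 that did not pass (limma adjusted p = 0.181). NOTCH3, a receptor that is itself a Notch target, had a log2 change of 1.91 (limma adjusted p = 0.0718; 0.0392 with the block). The second HEYL probe set, 220662_s_at, and the second NOTCH3 probe set, 203237_s_at, were near background, with changes of 0.19 and 0.14. Adjusted over the list alone, 7 members were higher and 1 was lower, HES7, at 37.4 in Jag1 arrays and 93.9 in controls; with the block 9 were higher and 3 lower, SOX9 and CCND1 with HES7. The median log2 change of the list was 0.20 and the camera adjusted p 3.34e-06, but the adjusted p = 0.115 with an estimated correlation. That correlation was -0.034, below the preset one, so a higher correlation does not explain the larger p. Of the 44 other members of the Notch pathway, namely its ligands, receptors and machinery, 0 passed, and their median was -0.11 (camera adjusted p = 0.602); adjusted over the list alone 0 passed, and with the block 1, CNTN1, was higher.

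**Figure D2:**
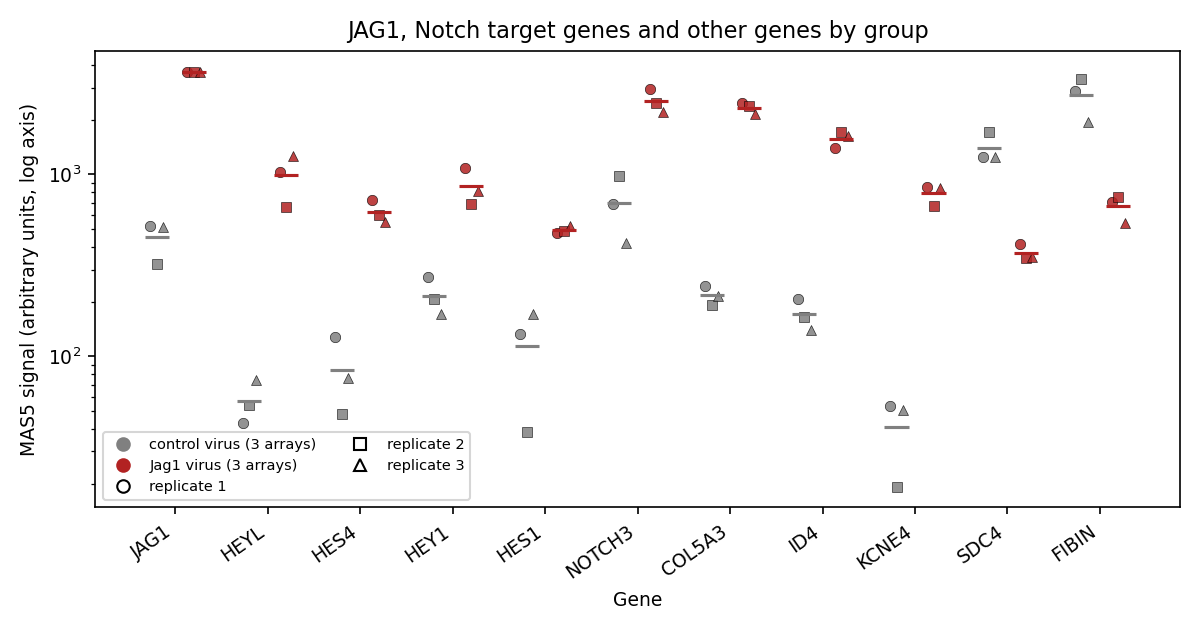
MAS5 signal per array on a log axis for JAG1, Notch target genes and other named genes, with 3 control and 3 Jag1 arrays; bars mark the group means and symbols the replicate number. HEYL means are 56.9 in controls and 987 in Jag1 arrays, and SDC4 means are 1403 and 370.

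Markers of decidualization, the differentiation of stromal cells that prepares the uterus for implantation, did not pass the list test. Of 39 measured, 0 passed limma's test over all genes and 0 passed when adjusted over the list alone. PRL, the classical secreted marker, had signals of 80.8 ± 9.83 in Jag1 arrays and 81.8 ± 4.81 in controls, a log2 change of -0.02 ± 0.229 (SE). IGFBP1, the other classical marker, had 114 ± 40.7 and 36.0 ± 24.2, a change of 1.37 ± 0.384 (limma adjusted p = 0.474). Its control mean lay within the range of the bacterial controls, as did both means of its second probe set, 237989_at. The PRL signals were little above the highest bacterial control, 66.2, which limits what these markers can show. The smallest p-values of the list also belonged to LAMA4, a laminin chain (1.48), INHBA, a subunit of activin (0.67), and the transcription factor CEBPD (-0.87), with limma adjusted p-values of 0.239, 0.556 and 0.572. With the block, LAMA4 passed over all genes (limma adjusted p = 0.0472). With the block, and adjusted over the list alone, 4 were higher (LAMA4, IGFBP1, IGFBP3 and INHBA) and 2 lower (CEBPD and TIMP3). The list's median was -0.09 while its mean was 0.07 and the camera direction was upward (adjusted p = 0.836). Of the 20 endometrial transcription factors and steroid receptors, 0 passed, with a median of -0.09 (camera adjusted p = 0.846, direction upward).

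Cell cycle genes were lower as a group in Jag1 cells. Of 50 measured, 48 were lower, 41 of them in every numbered pair, and the median log2 change was -0.64. The smallest p-values belonged to RRM2, a subunit of ribonucleotide reductase, at 392 ± 74.7 in Jag1 arrays and 819 ± 51.7 in controls (SD, n = 3 each), and to CDCA8, a member of the chromosomal passenger complex, at 19.2 ± 7.19 and 122 ± 56.6. Among the mitotic cyclins, CCNB2 had signals of 202 ± 36.7 and 416 ± 27.8, and CCNB1 had a log2 change of -0.82 ± 0.214 (SE). None of the 50 passed limma's test over all genes (adjusted p = 0.142 for RRM2), and 24 were lower when adjusted over the list alone (27 with the block). The camera adjusted p was 3.07e-24, but the adjusted p = 0.196 with an estimated correlation, which was 0.265 in this list. The mean level of the list was lower in Jag1 arrays by -0.73, -0.48 and -0.66 in the 3 numbered pairs (exact permutation p = 0.1 between groups, the smallest possible). Of 18 genes of the p53 response and growth arrest, 0 passed, with a median of 0.22 (camera adjusted p = 0.126), and 1 was higher when adjusted over the list alone. The list passed only without control replicate 1 (camera adjusted p = 0.0197). The higher member was CDKN2B, an inhibitor of the G1 cyclin-dependent kinases, at 2328 ± 231 in Jag1 arrays and 450 ± 263 in controls, a log2 change of 2.55 ± 0.464 (limma adjusted p = 0.144).

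**Figure D3:**
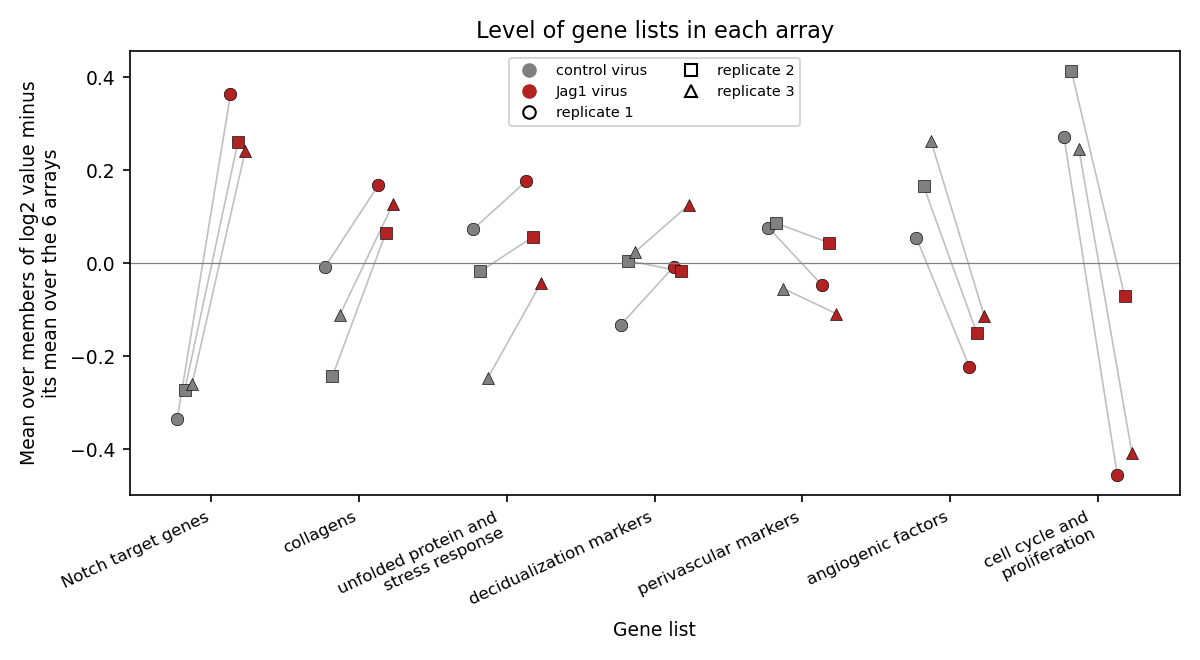
Mean over the members of a gene list of the log2 value minus its mean over the 6 arrays, for each array, with lines joining arrays of the same replicate number. Cell cycle genes average -0.31 in Jag1 arrays and 0.31 in controls, and Notch target genes 0.29 and -0.29.

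Collagen genes were higher as a group, led by COL5A3, and the list was not tested without that gene. Of 27 measured, 20 were higher, 1 passed the test over all genes, and the same number passed when adjusted over the list alone (2 with the block, COL5A3 and COL18A1). COL18A1, the precursor of endostatin, had a log2 change of 0.70 ± 0.185 (SE), and the short-chain collagens COL8A1 and COL8A2 had 0.92 ± 0.361 and -0.92 ± 0.274, with limma adjusted p-values of 0.401, 0.804 and 0.534. The list's median was 0.12, its mean 0.24 and its camera adjusted p 0.0104, but the adjusted p = 0.196 with an estimated correlation. That correlation was 0.0069, below the preset 0.01, so a higher correlation does not explain the larger p. The call also ended without Jag1 replicate 3 (0.0518), control replicate 2 (0.108) or control replicate 3 (0.104). Of 48 non-collagen matrix proteins and integrins, 0 passed, with a median of -0.01, a mean of 0.01 and an upward camera direction (adjusted p = 0.846). Adjusted over the list alone, 1 was higher: NID2, a basement membrane nidogen, at 4009 ± 894 in Jag1 arrays and 878 ± 542 in controls (limma adjusted p = 0.129; 0.0428 with the block). With the block, NID2 and ITGA1 were higher and LOXL4 was lower when adjusted over the list alone. Of 39 matrix metalloproteinases, ADAMs and inhibitors, 0 passed, with a median of 0.01 (camera adjusted p = 0.836). No member passed when adjusted over the list alone, and with the block MMP16 and ADAMTS2 were higher and PLAUR was lower.

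Angiogenic factors were lower as a group, although their only member past the test rose. EDN1, the vasoconstrictor endothelin, rose from a signal of 421 ± 93.6 to 1310 ± 181 (SD, n = 3 each; log2 change 1.61 ± 0.207, SE; limma adjusted p = 0.0383, and 0.0536 with the block). Its other probe sets, 218995_s_at and 1564630_at, had 1.01 and 0.52 and did not pass in the fit over all probe sets (limma adjusted p = 1.00 for both), where the tested one, 222802_at, had 0.0708. With the mean of probe sets, the change of EDN1 was 1.05 (limma adjusted p = 0.262). The guidance factor SLIT2 had a log2 change of -1.74 ± 0.243 (limma adjusted p = 0.0549), the growth factor FGF7 -2.01 ± 0.407 (0.197), and the VEGF receptor FLT1 1.74 ± 0.334 (0.175). VEGFC, a lymphangiogenic growth factor, had -1.44 (limma adjusted p = 0.377) and passed with the block (0.0477). Of 35 measured, 24 were lower, with a median of -0.41, and adjusted over the list alone 3 were higher and 7 lower (3 and 9 with the block). The camera adjusted p was 0.00225, but the adjusted p = 0.196 with an estimated correlation. That correlation was 0.0076, below the preset 0.01, so a higher correlation does not explain the larger p. Without control replicate 3 the camera adjusted p was 0.113.

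Genes of the unfolded protein and stress response were higher as a group by a small amount. SLC7A11, the cystine transporter, had signals of 4629 ± 1337 in Jag1 arrays and 1763 ± 136 in controls (log2 change 1.35 ± 0.221, SE). ASNS, asparagine synthetase, had a change of 0.82, the oxidoreductase NQO1 0.59 and the pseudokinase TRIB3 1.12. Of 32 measured, 19 were higher, with a median of 0.13, and 0 passed limma's test over all genes (adjusted p = 0.10 for SLC7A11). Adjusted over the list alone, 1 was higher, SLC7A11, and with the block ASNS, NQO1 and TRIB3 were as well. The camera adjusted p was 0.0340, but the adjusted p = 0.440 with an estimated correlation, which was 0.029. The call also ended without Jag1 replicate 1 (0.190), Jag1 replicate 2 (0.0506), control replicate 2 (0.0533) or control replicate 3 (0.712), and after quantile normalization (0.333).

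The remaining lists did not pass the list test, although the smooth muscle list passed upwards with every probe set (camera adjusted p = 0.0174), without control replicate 2 (0.0197), and with the block without its second pair (0.00397). In the TGF-beta and BMP pathway, 2 of 36 members passed, ID4 and TGFB2, a growth factor of the TGF-beta family, which rose from 1405 ± 92.5 to 3729 ± 536 (SD, n = 3 each; limma adjusted p = 0.0372); the list's camera adjusted p was 0.567. Adjusted over the list alone, SMAD6, an inhibitor of BMP signalling (log2 change -1.12), and the receptor TGFBR2 (-0.67) were lower as well, and with the block so were NOG and ID2. In the insulin-like growth factor system, 1 of 14 passed: STC2, a secreted inhibitor of the IGFBP-cleaving protease PAPP-A, rose from 848 ± 33.4 to 2574 ± 466 (limma adjusted p = 0.0265; camera adjusted p = 0.836). With the block, IGF1 was lower when adjusted over the list alone. Among 42 cytokines and chemokines, 0 passed, and adjusted over the list alone 1 was higher, TNFAIP3, an inhibitor of NF-kappaB signalling (log2 change 0.95; camera adjusted p = 0.846). No member passed among 45 interferon-stimulated genes (camera adjusted p = 0.602), 40 Wnt pathway genes (0.602), 30 smooth muscle and contractile genes (0.285), 32 hypoxia and glycolysis genes (0.511), 26 genes of sterol and fatty acid synthesis (0.988) or 28 immediate-early genes (0.875). Adjusted over the list alone, 0 members of these lists passed, except IER3 (log2 change 0.99) and the phosphatase DUSP4 (-1.05) among the immediate-early genes. With the block, SGK1 was also higher and EGR1 lower among these when adjusted over the list alone, VLDLR and SLC2A1 were higher among hypoxia and glycolysis genes, and DKK1 was lower among Wnt pathway genes.

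Markers of other cell types did not pass the list test. The median signal of epithelial markers was 30.5 ± 9.62 in Jag1 arrays and 31.2 ± 4.29 in controls (SD, n = 3 each), that of endothelial markers 19.0 ± 4.95 and 24.7 ± 6.22, that of leukocyte markers 36.1 ± 10.6 and 41.7 ± 3.92, and that of perivascular markers 67.9 ± 7.34 and 77.4 ± 7.70. Markers of stromal fibroblasts had medians of 4642 ± 258 and 5425 ± 771 (exact permutation p = 0.1, the smallest possible). Yet 15 of these 23 markers were higher and 8 lower, with a median log2 change of 0.07. The mean log2 level of that list gave an exact permutation p of 0.8. Of the 26 epithelial, 22 endothelial, 23 leukocyte, 15 perivascular and 23 stromal fibroblast markers, 0 passed limma's test, and the camera adjusted p-values were 0.836, 0.567, 0.902, 0.836 and 0.988. Adjusted over the list alone, 2 epithelial markers were lower, the keratin KRT19 (log2 change -1.21) and the protease inhibitor SPINT2 (-1.32), and so was 1 perivascular marker, the aminopeptidase ANPEP (-0.97).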

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

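The RNA quality covariate and the block fit without the second pair were tests chosen after the results were seen. The cause of each shift below was not tested, except where fewer samples or genes or a looser threshold make it. Against 22 genes higher and 4 lower, counts were 12 and 1 with a pseudocount of 64, 12 and 2 without the intensity trend, 60 and 16 with array weights, and 36 and 10 at a threshold of 0.1. Genes lower numbered 8 with the filter on dim genes, and 2 each with quantile normalization, every probe set, and the mean of probe sets. They numbered 17 with the replicate block and 10 with the block and quantile normalization. The block without its second pair, which leaves 1 residual degree of freedom, gave 158 and 157. Leaving out 1 array gave 4 to 21 higher and 0 to 2 lower, with fewer samples. The JAG1 change of 216268_s_at ranged from 2.78 to 3.12 in those fits. With an estimated correlation, list p-values were 0.115 for Notch targets, 0.196 for collagens, cell cycle and angiogenic genes, and 0.440 for the stress response. For Notch targets, collagens and angiogenic genes the estimate was below the preset 0.01, so more than the correlation differs between these settings. The p-values with an estimated correlation therefore do not measure the effect of correlation alone, in any of the lists. Array weights gave 0.207 for collagens, 0.0667 for angiogenic genes and 0.476 for the stress response, and the block without its second pair gave 0.0549 for collagens. The stress response had 0.0773 with the filter, 0.333 with quantile normalization, 0.0863 with median scaling, 0.0503 with the mean of probe sets, and 0.206 with the block and quantile normalization. Leaving out 1 array gave 0.00502 to 0.108 for collagens, 0.000665 to 0.113 for angiogenic genes, and 0.00502 to 0.712 for the stress response. The block changed no call of a list. Smooth muscle genes gained a call with every probe set, without control replicate 2, and with the block without its second pair, and the p53 list without control replicate 1. Of 682 values of named genes under alternatives, 562 kept their direction and side of the threshold, 85 lost and 29 gained a call, 6 values with no call changed sign, and no called value did. Signals near those of the bacterial controls, up to 66.2, limit what could be seen for dim genes.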

Other observations

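The tests of scaling, RNA quality, the response to Jag1, perivascular cells and the splits of the arrays were chosen only after the results they bear on were seen. The members of the metallothionein and cGMP sets were fixed after genes of each had been seen to move, and the tests of SLC30A1 and of the remaining cGMP genes before their values were seen. The heparan sulfate proteoglycans SDC2 and SDC4 changed in opposite directions. SDC2 rose from a signal of 1600 ± 579 to 7470 ± 1073 (SD, n = 3 each; log2 change 2.28 ± 0.293, SE; limma adjusted p = 0.0383), while SDC4 fell by 1.86 on the log2 scale. Other rises were in PLXDC1, a transmembrane plexin domain protein (2.32), the nucleotide sugar receptor P2RY14 (1.98, from control signals within the range of the bacterial controls), DEPTOR, an inhibitor of mTOR (1.76), and NPR3, the natriuretic peptide clearance receptor (1.45), with limma adjusted p-values of 0.0139, 0.0487, 0.0383 and 0.0383. P2RY14, DEPTOR and NPR3 passed in 0 of the fits that left out 1 array.

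With the replicate number as a block, further genes passed. The neurofilament genes NEFM and NEFL were lower, at 493 ± 219 against 3304 ± 2062 and 68.8 ± 26.8 against 343 ± 75.8 (SD, n = 3 each; limma adjusted p with the block 0.0162 and 0.0229). MEST, an imprinted gene, was lower at 1583 ± 747 against 4632 ± 2358, and so was CEMIP, a hyaluronan-degrading protein, at 625 ± 514 against 2039 ± 1563 (limma adjusted p with the block 0.0188 for both). The protease CTSC was higher at 8345 ± 1528 against 2501 ± 661 (0.0201). Without the block their limma adjusted p-values were 0.240, 0.0586, 0.597, 0.747 and 0.0508. The other neurofilament genes looked at, NEFH and INA, had log2 changes of 0.03 and -0.26 and did not pass with the block (limma adjusted p = 0.982 and 0.754).

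For the count of genes past the threshold, the 3 arrays against 3 allow 10 splits, too few for a share under 0.05. The real split gave 26 genes and the highest of the other splits 0, so 1 of the 10 splits gave as many genes.

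The first pattern was the lower level of cell cycle genes in Jag1 arrays. Scaling between arrays is argued against, since the list's median was still -0.58 after quantile normalization. RNA quality, as measured by the ACTB ratio, is argued against as the whole cause, since the median was -0.65 with that ratio as a covariate. A response of the infected cells to Jag1 stays open: the level was lower in the Jag1 array of 3 of the 3 numbered pairs, but since the groups did not overlap any pairing gives this, so it tests nothing. Differences between the 2 virus preparations, such as titre, lie with the groups and were not tested.

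The second pattern was in metallothioneins, small metal-binding proteins, of which 9 of 10 measured were lower, with a median of -1.64; MT1G, MT1M and MT4, the last of them the 1 that was higher, had mean signals within the range of the bacterial controls. The median was -1.67 after quantile normalization and -1.57 after median scaling. With the block 6 passed limma's test, among them MT2A, at 2504 ± 1343 in Jag1 arrays and 8893 ± 2427 in controls (SD, n = 3 each); without it, 0 passed. All 6 were measured by probe sets of the cross-hybridising kind, so they may share signal and need not be 6 independent falls. The members measured by other probe sets, MT1G (log2 change -0.52), MT1M (-0.23), MT3 (-0.33) and MT4 (0.11), did not pass with the block. Of these only MT3 lay above the bacterial controls, at 96.5 ± 28.1 in Jag1 arrays and 123 ± 6.82 in controls. SLC30A1, a zinc-responsive transporter that is no metallothionein, had a log2 change of -0.28 with the block (limma unadjusted p = 0.115), so a lower metal response and signal shared between paralogs cannot be told apart by it.

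The third pattern, picked from genes already seen, was in EBF1, HEYL and NOTCH3, which are also expressed in mural cells of vessels; EBF1 and HEYL rose, and NOTCH3 did not pass (limma adjusted p = 0.0718), although it did with the block (0.0392) and under some other alternatives. More perivascular cells in the Jag1 cultures are argued against by the fixed list of 15 perivascular markers, whose highest log2 change was 0.58, with a median of -0.09. Its most abundant member, RGS4, had signals of 2953 ± 1320 in Jag1 arrays and 2938 ± 254 in controls (SD, n = 3 each), and CSPG4 454 ± 14.3 and 454 ± 56.0. In controls 9 of the 15 markers already lay above the highest bacterial control, so a small share of such cells would not be seen. A change of these genes within the stromal cells may be a response to Jag1, which is a hypothesis.

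A theme picked from genes already seen was cGMP signalling. Of its genes only NPR3, the natriuretic peptide clearance receptor, passed without the block. Higher RNA of these genes does not give the direction of any change in the signalling. GUCY1A2, a subunit of soluble guanylate cyclase, had a log2 change of 2.60 (limma adjusted p = 0.0613; 0.0201 with the block), PRKG1, the cGMP-dependent kinase, 1.58 (0.175; 0.0428) and PDE3A 1.75 (0.0642; 0.0958). The control means of GUCY1A2, PDE3A and GUCY1B1 (16.4, 49.4 and 36.1) lay within the range of the bacterial controls, so the sizes of their changes depend on the pseudocount. Whether the rest of the pathway rises too was tested on 7 members not looked at before, with a median of 0.03, 4 higher and 3 lower. With a preset correlation of 0.01 between genes, the camera list test of limma gave p = 0.408, and 0.446 with an estimated one. This met the bound set beforehand for rejecting the hypothesis, a p at or above 0.05. That bound was set aside only after its value was seen, and the rule that most members must exceed the bacterial controls was added then. The bound was poorly chosen, since a missed threshold does not show an absence of change and 4 of the 7 had mean signals within the range of the bacterial controls in both groups. Of the other 3, GUCY1B1, the partner subunit of the cyclase, had 2.02 ± 0.349 (SE; limma adjusted p = 0.127; 0.0524 with the block), PDE5A 0.03 and PDE3B -0.25. The question stays open for the pathway.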
